A study of Mus musculus with 5 samples.

How the data were processed

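Gene expression was measured on single-channel Affymetrix mouse expression arrays in tumour cells of the mouse prostate. Per the labels, tumours were dissociated and the tumour cells isolated with EpCAM beads, all on ice, and total RNA was extracted with a column kit and labelled with biotin. The 5 arrays came from 5 mice with separate animal numbers, 3 of the genotype called nDKO and 2 of the genotype called nTKO, and the age of each mouse is given in weeks.

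The deposited values are log2 signals, 1 per probe set and array, rounded to 2 decimals. Per the submitters' processing notes they were made with RMA and the Transcriptome Analysis Console, with versions not given in the sources used here. RMA subtracts background, quantile-normalizes the probes and summarises them per probe set, so a gain or loss shared by most genes would not be seen, and dim probe sets are drawn towards a common floor. Of the genes tested, 26% had the same value on at least 3 of the 5 arrays (39.5% of the genes below the median level and 12.4% of the others), which makes the spread of those genes small. The floor and the rounding may account for such ties, which was not tested. No scanner files were used here.

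The table held 45037 probe sets. In the platform annotation, 34945 of these had 1 gene symbol, 932 had several and 9160 had none. Gene identifiers of 34741 probe sets were found in a gene table of the assembly GRCm38.p6, and 0 symbols had to be updated. A gene was represented by its probe set with exactly 1 symbol and the highest mean over all 5 arrays, which gave 18193 genes, 9010 of them with more than 1 probe set. Trp53 had no probe set with a single symbol and was not analysed here, and some items are not reported here.

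The genotypes were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend on the deposited log2 values, with no filter, no covariate and a threshold of 0.05 on the Benjamini-Hochberg adjusted p, two-sided. The fit had 3 residual degrees of freedom per gene and 1.23 from the prior. Genes with a fold of at least 2 and an unadjusted p under 0.05, the default filter of the authors' software, were counted beside it. Gene lists (45 lists, 753 genes, 670 measured) were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 44 lists with at least 5 measured members, and again with an estimated correlation and with fry.

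Simulated arrays had the means of the 18193 genes, their variances as moderated by eBayes rather than their own, and 200 genes changed. On these, the comparison of nTKO with nDKO recovered 75.4% of changes of 1 log2 unit, 93.6% of changes of 2 and 96.7% of changes of 3 at a limma adjusted p under 0.05. Simulated genes varied independently of each other, which the real ones did not. The simulated noise was normal, and the 200 planted changes make the adjusted threshold easier to pass. In the real data Pygo2, at -1.84, had a limma adjusted p of 0.853. The recovered shares therefore do not tell which share of real changes of these sizes the comparison can find. A simulated shift of -0.5 in the basal epithelium list of the same comparison was called by camera in 8 of 10 draws with the preset correlation and in 0 of 10 with an estimated one.

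The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names targeted genes, among them Pygo2 and Smad4, then up to 12 genes per direction whose groups do not overlap. These are taken by size among those with an adjusted p under 0.05 and are otherwise filled by unadjusted p from genes with a log2 fold change of at least 1, leaving out predicted genes. It also names up to 4 members of each described list with the smallest p, and a few genes fixed in advance whatever their values, among them Kit, Ido1, Trp53, Sp1 and Cd274. Which lists are described, and how many members of each, was chosen after the values were seen. The alternatives were a filter at the median gene level of 6.32, quantile normalization, median centring, eBayes without the trend, robust eBayes, array weights, log2 age as a covariate, the replicate number as a block, all probe sets, and leaving out each mouse. Added after seeing the data were leaving out the 2 arrays that stand apart, a pair of mice of like age, and the other probe sets of a named gene.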

Results

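Expression was compared between epithelial tumour cells of mouse prostates with 2 genotypes, both on a C57BL/6 background. In nDKO mice, the prostate-specific Probasin driver deletes floxed alleles that include Smad4, the common mediator of TGF-beta signalling. In nTKO mice, floxed Pygo2 is deleted as well. Pygo2 encodes a PHD-finger protein that reads methylated histone H3 and acts as a co-activator of beta-catenin, and the comparison asks which transcripts of the tumour cells differ when it is lost. The nDKO mice were 15.86, 10.71 and 10.71 weeks old and the nTKO mice 31.43 and 16 weeks, so that age and genotype are partly confounded. Array medians lay between 4.94 and 4.98 on the log2 scale.

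Pygo2 itself was lower in both nTKO mice than in every nDKO mouse. Its signal was 8.65, 8.62 and 8.72 in nDKO cells and 7.30 and 6.35 in nTKO cells, a log2 fold change of -1.84 (SE 0.30), which leaves 28% of the nDKO signal (38.9% and 20.1% in the 2 nTKO mice). Smad4 kept a signal in both groups, with means of 9.80 (SD 0.14) in nDKO and 10.07 (SD 0.43) in nTKO cells (log2 fold change 0.27, limma adjusted p = 0.853), and the difference was 0.77 with log2 age as a covariate, 0.74 in the pair of like age (nTKO 2 minus nDKO 1) and -0.037 without nTKO 2. In the limma fit, Pygo2 had an unadjusted p of 0.00314 and an adjusted p of 0.853 over all genes, and 0.00628 adjusted over the list alone (the 2 targeted genes measured). It has 1 probe set, and the position of that probe set relative to the deleted part is not known here, so the signal left cannot be read as the share of cells that kept the gene. The same holds for the Smad4 probe sets.

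**Figure D1:**
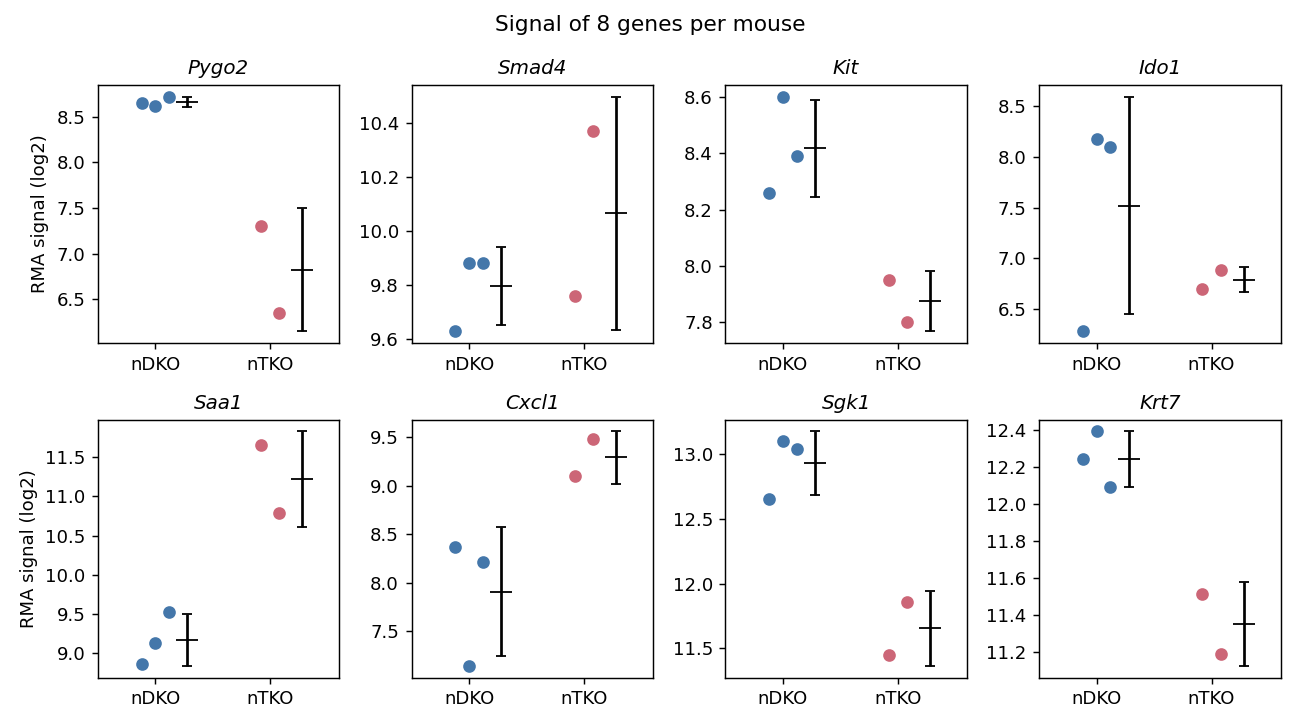
RMA signal (log2) of 8 genes in each mouse (points), with mean and SD beside them (bars), for 3 nDKO and 2 nTKO arrays; vertical axes differ between panels and do not start at 0. Pygo2 was 8.62 to 8.72 in nDKO and 6.35 to 7.30 in nTKO cells, and Ido1 of nDKO 1 (6.28) lay below both nTKO values.

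The rule for named genes took only genes whose groups do not overlap and whose log2 fold change is at least 1 in size. Places were filled by unadjusted p, so some larger differences, as that of Ccl28 (1.49), were left out. Among the genes so named, the secreted acute phase proteins Saa1 and Saa2 were higher in nTKO cells, by log2 fold changes of 2.05 (SE 0.34) and 1.56 (SE 0.55). Most of the difference of Saa2 came from nTKO 1 (6.32, against 4.73 in nTKO 2 and 3.53 to 4.19 in nDKO cells), and it was 0.76 without that mouse. The neutrophil-attracting chemokine Cxcl1 (1.38), the cell cycle regulator Ccnd2, cyclin D2 (1.12), the adhesion molecule Chl1 (1.05) and the class I-like H2-Q10 (1.32) were also higher in both nTKO mice than in every nDKO mouse. Further genes on that side were Wdfy1 (1.40), Tmem267 (1.78), BC023105 (1.50), LOC664787 (1.13), Mtcl1 (1.06) and Pknox2 (1.05). Lower in both nTKO mice were the serum- and glucocorticoid-regulated kinase Sgk1 (-1.28, SE 0.21), the surface glycoproteins Msln, mesothelin (-1.35), and Gp2 (-1.25), the fucosyltransferases Fut4 (-1.08) and Fut9 (-1.03), and the secreted protease Htra1 (-1.24). Tmem45b (-1.18), Rps4l (-1.11), Rsrp1 (-1.04), AA986860 (-1.04) and Dbp (-1.03) were lower as well. Other probe sets gave a like change for Saa1 (2.24), for most of those of Ccnd2 and for some of Wdfy1 (1.62 and 1.38) and Cxcl1 (1.63). Smaller changes came from other probe sets of Rsrp1 (-0.20 and -0.03), AA986860 (-0.13), Chl1 (0.54, 0.18 and 0.042), Fut9 (-0.29 and -0.23), Fut4 (-0.53), Dbp (-0.50), Mtcl1 (0.41), Htra1 (-0.86), Cxcl1 (0.12), Wdfy1 (0.61 and 0.033), Ccnd2 (-0.03) and Pknox2 (-0.038).

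Several of these differences changed in the settings for age or with 1 mouse left out. The oldest mouse of each genotype, nDKO 1 and nTKO 1, is also the array that stands apart, so age cannot be told from other differences between mice. The pair of like age sets nDKO 1 against nTKO 2, at opposite ends of the first principal component (36.9 and -23.6). The covariate gave values close to that pair for many genes, so the 2 settings are not separate checks. With log2 age as a covariate, and in the pair of like age, Rps4l was -0.31 and -0.24, Rsrp1 -0.52 and -0.59, Fut4 -0.56 and -0.38, Sgk1 -0.82 and -0.79, and Htra1 -0.72 and -0.93. On the higher side, Ccnd2 was 0.72 and 0.56, LOC664787 0.75 and 0.61, and Saa2 0.89 and 1.20. Other differences were larger in the same 2 settings, with Dbp at -1.83 and -1.74, Gp2 at -2.21 and -2.22, Fut9 at -1.55 and -1.57, H2-Q10 at 2.37 and 2.26 and Mtcl1 at 1.75 and 1.87. Without nTKO 2, H2-Q10 was 0.60, Gp2 -0.75 and Dbp -0.49. Without nTKO 1, BC023105 was 0.96, Htra1 -0.67, Rsrp1 -0.66, H2-Q10 2.03 and Dbp -1.58. Msln (-0.79) and Tmem45b (-0.73) were smaller without both nDKO 1 and nTKO 1.

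None of these genes passed the test across the genome. With limma, 0 of 18193 genes had an adjusted p under 0.05 (smallest 0.853). An unadjusted p under 0.05 was found for 689 genes, 447 higher and 242 lower, where chance alone gives 910. The split followed the scaling, with 303 of 598 higher after quantile normalization and 236 of 595 after median centring. A fold of at least 2 with an unadjusted p under 0.05 was found for 24 genes, 12 higher and 12 lower. The groups did not overlap for 12.8% of genes, where chance gives 20% for values without ties. Ties lower that share, and 26% of genes had the same value on at least 3 arrays, so 12.8% cannot be read as a shortfall. An exact permutation test of a single gene cannot go below 0.1 with 10 splits. The count of 24 became 64 without nTKO 1, 107 without nTKO 2 and 354 with log2 age as a covariate.

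Basal epithelial genes were lower as a list in nTKO cells, the 1 list called of the 44 tested (camera adjusted p = 0.0168). The call was lost with an estimated correlation (camera adjusted p = 0.996, unadjusted 0.152). That setting found a simulated shift of -0.5 in this list in 0 of 10 draws, so its p-values cannot decide for or against a list here. The array medians of the list overlapped between the genotypes, with 8.96, 8.21 and 7.85 in nDKO and 8.35 and 7.90 in nTKO cells. They were highest in nDKO 1 and nTKO 1, as were those of the squamous list. Of 14 measured members, 12 were lower and 2 higher, with a median log2 fold change of -0.32, which was -0.038 without nDKO 1 (-0.52 to -0.038 with 1 mouse left out). Krt15, a basal keratin, was lower in both nTKO mice than in every nDKO mouse (-0.51, SE 0.19), and the surface protein Pdpn (-0.58) and the laminin-binding integrins Itgb4 (-0.40) and Itga6 (-0.25) had lower means. The differences of Pdpn and Itgb4 came from nTKO 1 (6.90 and 8.04, against 7.85 and 8.74 in nTKO 2), and were -0.11 and -0.047 without it, while Krt15 was -0.25 without nTKO 2 and -0.93 with log2 age as a covariate. Itga6 was -0.12 without nTKO 1. Krt15, Pdpn, Itgb4 and Itga6 were named for having the smallest p in the list. Other basal markers, Krt5 (-0.16), Krt14 (-0.62) and Aqp3 (-0.048), were highest in nDKO 1 and nTKO 1. So were the 2 higher members, Krt17 (0.26) and Trp63 (0.15). Of the members, 0 passed over all genes and 0 adjusted over the list alone. The adjusted p was 0.609 without nDKO 1, which had the highest median of the list (8.96), 0.385 without nTKO 1, 0.0788 after quantile normalization, 0.0855 after median centring and 0.257 with array weights, in a range of 1.28e-05 to 0.996 over all alternatives.

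Luminal and androgen-related genes were not called as lists. Of 14 luminal genes, 8 were lower and 6 higher (median -0.073, camera adjusted p = 0.200), and the list was called lower without nTKO 2. Its median lay between -0.26 and 0.11 with 1 mouse left out. The simple-epithelial keratin Krt7 stood out, at 12.24 (SD 0.15) in nDKO and 11.35 (SD 0.23) in nTKO cells. Its log2 fold change was -0.89 (SE 0.15) with a limma adjusted p of 0.853 over all genes and 0.042 adjusted over the list alone. Over the 45 lists, each adjusted alone, 2 members passed in this way, Krt7 and the deleted Pygo2. With so many lists, the pass of Krt7 may be due to chance. Androgen-responsive genes were split, 9 higher and 8 lower (camera adjusted p = 0.817), and the glucocorticoid- and androgen-induced Tsc22d3 was lower by its 2 brightest probe sets (-0.48 and -0.92), the first of which gave -0.31 without nTKO 2. Squamous differentiation genes had a median of -0.19 (-1.28 to 0.58 with 1 mouse left out, camera adjusted p = 0.426), with array medians of 9.84 in nDKO 1 and 8.55 in nTKO 1 against 5.30 to 6.09 in the other 3. The squamous list was called lower with log2 age as a covariate, with the replicate block, without nDKO 3, without nTKO 1, and without both nDKO 1 and nTKO 1.

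**Figure D2:**
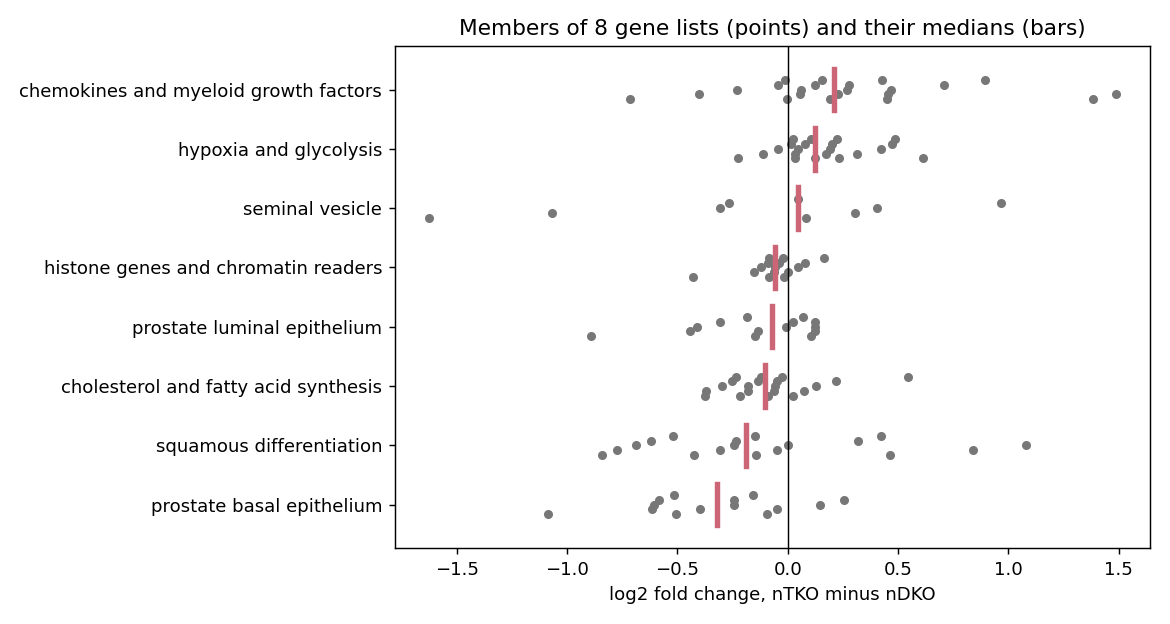
Log2 fold changes (nTKO minus nDKO, horizontal axis) of the measured members of 8 gene lists (points, spread vertically for visibility) and the median of each list (bars). The basal epithelium list has the lowest median, -0.32, and the chemokine list the highest, 0.21.

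None of the genes tied to the study's question passed the test over all genes. The receptor tyrosine kinase Kit was lower in both nTKO mice, at 8.42 (SD 0.17) in nDKO and 7.88 (SD 0.11) in nTKO cells (log2 fold change -0.54, SE 0.13, limma adjusted p = 0.853, 0.0114 before adjustment). The tryptophan-degrading enzyme Ido1 had a mean of 7.52 (SD 1.08) in nDKO and 6.79 (SD 0.13) in nTKO cells (log2 fold change -0.73, limma adjusted p = 0.855). Its nDKO values were 6.28, 8.18 and 8.10, so the difference lay within the spread of the nDKO mice. It was 0.28 with log2 age as a covariate, 0.60 in the pair of like age, -1.35 without nDKO 1 and -0.40 without nDKO 2. The transcription factor Sp1 differed by -0.11 (limma adjusted p = 0.853) and the checkpoint ligand Cd274, PD-L1, by 0.19 (limma adjusted p = 0.962), which was -0.61 without nTKO 1 and 0.99 without nTKO 2. Of 12 genes of the Kit, Ido1 and tryptophan list, 6 were higher and 6 lower (camera adjusted p = 0.652), and the list was called lower among genes at or above the median level.

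p53 target genes were split, 11 higher and 9 lower, with a median of 0.0092 (-0.16 to 0.21 with 1 mouse left out), a mean of -0.047 and a downward camera test (adjusted p = 0.534). The death receptor Fas was higher (0.34) and Ei24 lower (-0.23) in both nTKO mice, the latter at -0.087 with log2 age as a covariate and -0.09 in the pair of like age. The partners of Pygo2 in the Wnt complex had 7 genes higher and 4 lower (camera adjusted p = 0.971), with Tcf7l1, a DNA-binding repressor of Wnt targets, at 0.44 (0.22 with log2 age as a covariate and 0.20 in the pair of like age). Wnt target genes had 14 higher and 5 lower with a median of 0.012 (camera adjusted p = 0.964). The p53 list was called lower with log2 age as a covariate, without nTKO 1, and without both nDKO 1 and nTKO 1.

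Chemokine genes were higher on balance, 16 of 22, with a median of 0.21 that was 0 without nTKO 1 (0 to 0.39 with 1 mouse left out; camera p = 0.0273, adjusted p = 0.200, p = 0.397 with an estimated correlation), and the list was called higher after quantile normalization, after median centring and without nTKO 2. Besides Cxcl1, the neutrophil chemoattractants Cxcl2 (0.89, SE 0.37) and Cxcl15 (0.45, SE 0.15) were higher in both nTKO mice, with Cxcl2 at 0.50 without nTKO 1, the array with the highest neutrophil marker median. Interferon-stimulated genes were higher for 17 of 20 (median 0.18, -0.15 to 0.36 with 1 mouse left out, camera adjusted p = 0.813), among them Cxcl11 (1.36), which was high in nTKO 1 alone (8.57). Without nDKO 1, whose array median of this list was lowest, the interferon list and the class I antigen presentation list were called lower in nTKO cells, and with log2 age as a covariate both were called higher. Class I genes had a median of 0.072 with a downward camera test (adjusted p = 0.971). Checkpoint ligands had 9 higher and 5 lower, a median of 0.064 and a mean of -0.017 (camera adjusted p = 0.956). Among them, Nectin2 was at 0.31 (0.47 with log2 age as a covariate, 0.05 by its other probe set) and Tnfsf9 at 0.29 (0.15 without both nDKO 1 and nTKO 1).

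Hypoxia and glycolysis genes were higher for 18 of 21, with a median of 0.12 (0.063 to 0.30 with 1 mouse left out, camera p = 0.0143, adjusted p = 0.158, p = 0.412 with an estimated correlation). The list was called higher in 5 alternatives, with the filter at the median level, after quantile normalization, after median centring, without nDKO 2 and without nTKO 2. Bnip3, a mitophagy receptor, was higher by 0.49, the glycolytic regulator Pfkfb3 by 0.61 and the angiogenic factor Vegfa by 0.23, each in both nTKO mice. With log2 age as a covariate, Pfkfb3 was 0.26 and Vegfa 0.083, and without both nDKO 1 and nTKO 1 Bnip3 was 0.25. Phgdh, the first enzyme of serine synthesis, was higher by 0.61 (SE 0.10), with a limma adjusted p of 0.853 over all genes and 0.0655 adjusted over the list alone (PI3K, FoxO and mTORC1 genes, camera adjusted p = 0.817). Other probe sets of Phgdh gave 0.635, 0.31 and 0.34. Cholesterol and fatty acid genes were lower for 15 of 20 (median -0.10, -0.29 to 0.012 with 1 mouse left out, camera adjusted p = 0.158), including the regulator Srebf2 (-0.30) and the synthase Fdps (-0.38), whose values came mostly from nTKO 1 (-0.11 and 0.013 without it). Histone and chromatin reader genes were lower for 11 of 15 (median -0.058, -0.075 to -0.01 with 1 mouse left out, camera adjusted p = 0.158). The deacetylase Hdac1 was at -0.43 (-0.17 without nTKO 2 and -0.68 without nTKO 1). This list was called lower without nDKO 2 and without nDKO 3. The cholesterol list was called lower without nDKO 2 and without nTKO 2, and higher without both nDKO 1 and nTKO 1.

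Markers of other cells that the suspension could hold were not called in either direction. Neutrophil markers had array medians of 6.55, 6.43 and 6.81 in nDKO cells, 7.71 in nTKO 1 and 5.91 in nTKO 2 (camera adjusted p = 0.658), and the list was called higher without nTKO 2, and lower without nTKO 1 and with log2 age as a covariate. Macrophage markers were lower for 12 of 19 (median -0.065, -0.32 to 0.18 with 1 mouse left out, camera adjusted p = 0.658), with the complement gene C1qa at -0.95 (SE 0.47, -0.56 without nDKO 3), and the list was called lower without nDKO 2. T cell markers had array medians of 3.95 to 4.14 (camera adjusted p = 0.813) and mast cell markers 3.85 to 4.19 (adjusted p = 0.813). Fibroblast markers lay between 4.19 and 4.50 (camera adjusted p = 0.964). The medians of T cell, mast cell and fibroblast markers were below the array medians of 4.94 to 4.98. Dim probe sets may not respond, so the lack of a call does not show like amounts of these cells.

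The arrays themselves did not group by genotype. Pearson correlations across probe sets, which are not independent, were 0.995 to 0.996 among nDKO 2, nDKO 3 and nTKO 2, and 0.987 to 0.991 for any pair with nDKO 1 or nTKO 1. The first principal component held 52.1% of the variance and placed nDKO 1 (36.9) and nTKO 1 (16.7) against the other arrays (-14.5 to -23.6). The 12 genes with the largest positive loading on it, at the end of nDKO 1, include the keratins Krt10, Krt13 and Krt1. Genes at the negative end include the seminal vesicle transcripts Svs2, Sva and Svs6. Krt10 measured 13.03 in nDKO 1 and 13.04 in nTKO 1 against 6.71 to 6.93 in the others.

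**Figure D3:**
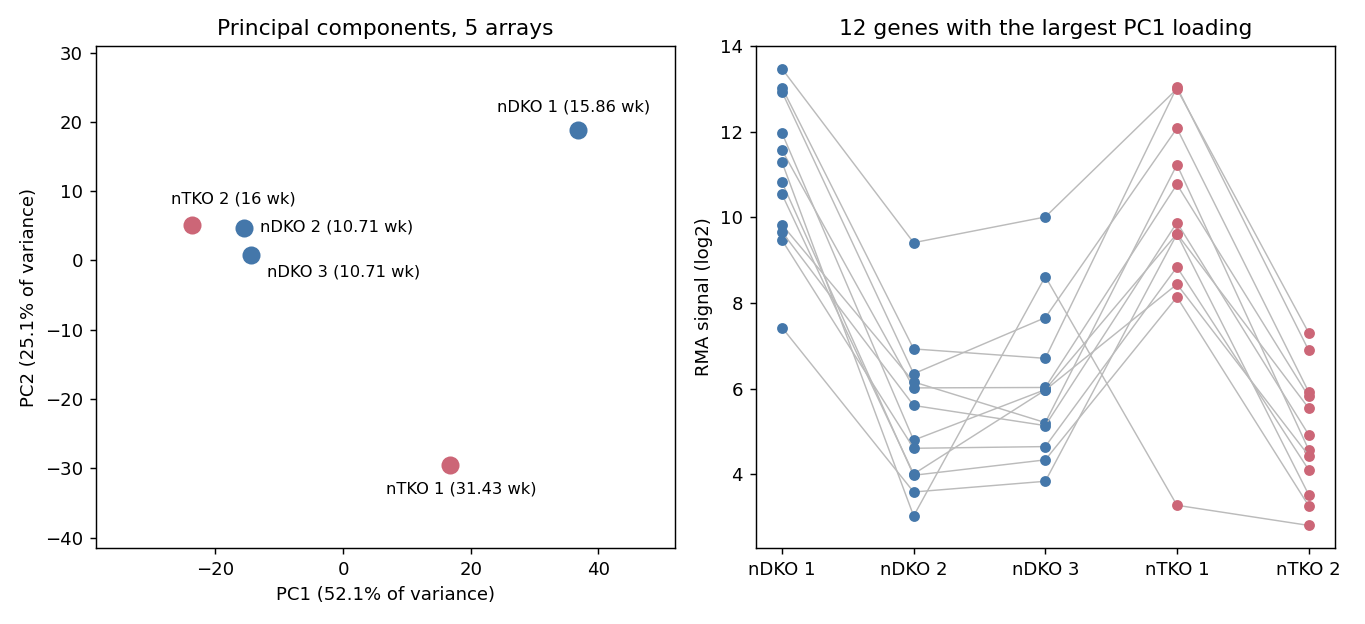
Left, the first and second principal components of the 5 arrays with the age of each mouse in weeks. Right, the RMA signal (log2) of the 12 genes with the largest positive loading on the first component, 1 line per gene, blue for nDKO and red for nTKO arrays. Most of these genes were high in nDKO 1 and nTKO 1, as Krt10 (13.03 and 13.04), while Prol1 was high in nDKO 1 and nDKO 3 (11.29 and 8.62).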

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

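The tests of age, genotype, seminal vesicle RNA and the neighbours of Pygo2 and AA986860 were chosen after the patterns were seen, and the bounds for age and genotype were set again, from a gap of 2 to the spread over genes, after their values were seen. Among probe sets with no gene symbol, which the comparisons of genes do not use, 2 were at least 2-fold higher and 5 at least 2-fold lower in nTKO cells with an unadjusted p under 0.05. Their genes were not analysed here.

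Of the 12 genes with the largest positive loading on the first component, 11 were highest in nDKO 1 and nTKO 1, among them Krt10, Krt13 and Krt1, while Prol1 measured 3.28 in nTKO 1 and 8.62 in nDKO 3. Epidermis in the suspension is argued against by 12 epidermal genes with a median gap of 0.04 between these arrays and the rest. The gap was 1.96 for Asprv1, 0.47 for Flg and 0.45 for Krt77, and between -0.133 and 0.155 for the others. This argument is weak, since the 12 genes had array medians of only 3.80 to 3.94, and dim probe sets may not respond. Age and genotype were tested on 14 members of the squamous list outside those 12, with a median gap of 1.12 and each highest in nDKO 1 or nTKO 1. Genotype as the whole account is argued against by median gaps of 1.62 within nTKO and 1.40 within nDKO, against 0.28 between genotypes (at least 1.12 more). Age as the whole account, acting alike in both genotypes, is argued against by mice of like age. There nTKO 2 was farther from nDKO 1 than from nDKO 2 and nDKO 3 by 1.50. Wilcoxon intervals over genes, which are not independent, lay above 0 (lower bounds 0.29, 0.53 and 0.66). However, nDKO 1 and nTKO 1 were the oldest mouse of each genotype (15.86 and 31.43 weeks), so age within a genotype stays open. The 14 genes share a list with some of the 12, so they are no independent check of which arrays stand apart. A squamous region in 2 of the tumours may account for the pattern and was not tested, and it stays open with other differences between mice.

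Seminal vesicle secretion transcripts differed between arrays, up to 14.08 for Svs5 in nDKO 3, the maximum of that array. A single source of seminal vesicle RNA in a varying share moves every transcript the same way, but from nTKO 1 to nTKO 2 the steps ran from 0.55 for Svs2 to -4.18 for Sva (a range of 4.73, against an SD of 0.46 over brighter genes), and from nDKO 2 to nTKO 2 from 0.35 to -3.63. This argues against a single source for what sets nTKO 2 apart, and from nDKO 3 to nTKO 2 Pate4 moved by -1.14 and Svs6 by -4.49, though to nTKO 1 they had moved alike (-1.44 and -1.22). Among the other 4 arrays no pair had such opposite steps, with ranges from 0.91 (nDKO 3 and nTKO 1) to 5.69 (nDKO 1 and nDKO 3), and since each probe set may have its own ceiling and baseline, the ranges leave a single source open there. Expression by prostate cells, or more than 1 source, were not tested.

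Genes beside Pygo2 were examined for variants of another strain carried along with the targeted allele. Of the 20 nearest measured genes in the order of GRCm38.p6, 2 had an unadjusted p under 0.05, Efna4 (-0.97) and the predicted gene Gm15417 (0.39), named after their values were seen. As many were found in 17.0% of 17621 windows across the genome, a window set after a wider look at the region, so chance placement may account for them. In the 11th to 40th genes on either side, 4 of 60 had such a p, as in 18.8% of windows, so linked variants may be present but cannot be told apart from chance with these counts. Beside AA986860, on another chromosome, 1 of the 20 nearest genes and 4 of the next 60 had such a p, as in 52.7% and 18.8% of windows, so linked variants are not excluded for its lower signal either.

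For the count of 24 genes past fold 2 and an unadjusted p under 0.05, the 10 splits of the 5 arrays into 3 and 2 are too few for a share under 0.05. At least 24 genes were found in 7 of the splits, the real one included, and the highest of the others, nDKO 1 and nTKO 1 against the rest, gave 215, which points to a structure of the samples, the one the first component had already shown.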

How the results depend on the processing

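Leaving out the 2 arrays that stand apart, the pair of like age and the other probe sets were chosen after seeing the data. The 0 genes at an adjusted p under 0.05 stayed 0 in all alternatives run, with 689 at an unadjusted p. The 24 genes past fold 2 became 354 with log2 age, 51 with all rows, 58 without both arrays that stand apart and 25 to 107 with 1 mouse left out (64 without nTKO 1, 107 without nTKO 2). The 1 called list became 3 with the filter, 2 with quantile normalization, 2 with median centring, 0 with array weights, 0 with all rows, 7 with log2 age, 3 without both arrays, 0 with an estimated correlation, 0 with fry and 2 to 6 with 1 mouse left out. The basal list's adjusted p was 0.0788 with quantile normalization, 0.0855 with median centring, 0.257 with array weights, 0.0752 with all rows, 0.874 without both arrays, 0.996 with an estimated correlation, 0.957 with fry and 0.00198 to 0.609 with 1 mouse left out (0.609 without nDKO 1, 0.385 without nTKO 1). Pygo2 stayed lower with p under 0.05 in every tested alternative, from -1.36 to -2.31 with 1 mouse left out, and measured -2.30 in the pair of like age. A lone nTKO array was assumed to vary like the nDKO arrays, and camera has no robust form. The replicate numbers were not taken as pairs of mice. Deviations of same-numbered arrays correlated 0.42 and 0.34, and those of nDKO 3 and nTKO 2 correlated 0.31. The deviations of the 2 nTKO arrays mirror each other, so these values cannot tell whether mice were paired. The replicate block (1 residual degree of freedom) gave 48 genes past fold 2 and 5 lists. Among named genes, none past the threshold, signs reversed for Cd274 (-0.52 with log2 age, -0.82 without both arrays, -0.61 to 0.99 with 1 mouse left out), Fdps (0.076 with log2 age, 0.035 without both arrays, -0.77 to 0.013 with 1 mouse left out) and Ido1 (0.28 with log2 age), for Itgb4 (0.01 without both arrays), and for Smad4 (-0.037 to 0.57 with 1 mouse left out). Other probe sets reversed for Ccnd2 (-0.03), Fdps (0.05), Pfkfb3 (-0.068), Pknox2 (-0.038), Sp1 (0.027), Tcf7l1 (-0.088) and Tsc22d3 (0.19). Of 840 values of named genes, 796 kept direction and call, or moved by less than 1 SD in the pair of like age, and 27 moved in that pair. With 0 genes called in any setting, the call could not change. Outside that pair the count of 796 therefore tells only of the sign, whatever the size. Itgb4 counted as kept at -0.044 with log2 age, against -0.40 in the main fit. Of 690 list medians, 60 moved. A median of an uncalled list counted as moved only past 1 SD of that list's nDKO array medians, whatever its sign. The squamous list, with nDKO array medians of 9.84, 6.09 and 5.96, counted as kept at -1.28 against -0.19 in the main fit. The count of 60 therefore does not tell how many medians were stable. The cause of these changes was not tested. Signal near the floor limits dim probe sets.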

Other observations

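S100a9, a neutrophil calcium-binding protein, measured 12.94 in nTKO 1 and 7.93 in nTKO 2, against 9.26 to 10.01 in nDKO cells, and Saa3 measured 11.84 and 9.88 against 8.21 to 9.49. Both were named after their values were seen, and the neutrophil markers had array medians of 7.71 in nTKO 1 and 5.91 in nTKO 2.

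The sets of acute phase and clock genes were written after Saa1, Saa2 and Dbp stood out and before the tests of the sets were run. A wider acute phase and NF-kB response was tested as a hypothesis for the higher Saa1 and Saa2, with 20 other genes of that kind. Of these, 14 were higher in nTKO cells and 6 lower, with a median of 0.14, a camera p of 0.384 and a p of 0.638 with an estimated correlation, so the response may or may not be wider than the Saa genes. A different phase of the circadian clock was tested for the lower Dbp. The 8 other genes of the clock output arm had a median of -0.014 (SD 0.21 over genes) and the Arntl arm 0.098, far from the -1.03 of Dbp, which argues against a shift of the whole clock shared by both mice. Per1 was lower in both nTKO mice (-0.34, limma unadjusted p of 0.00554), and Per3 (-0.31) and Tef (-0.38) had lower means. Against the nDKO means, nTKO 2 had a median of -0.24 for the output arm and -1.58 for Dbp, and nTKO 1 had 0.063 and -0.49. Per1 measured 7.34 in both nTKO mice, so a partial change, in nTKO 2 alone or in both mice, stays open.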
